A study of Rattus norvegicus with 4 samples.

How the data were processed

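The transcripts of rat articular cartilage and xiphoid cartilage were measured by RNA sequencing, with 2 libraries per tissue from Sprague-Dawley rats of 8 to 10 weeks. Per the labels' protocols, the cartilage was frozen on dry ice and RNA was extracted with Trizol. The labels state neither which joint was used nor whether the libraries came from separate animals or pools.

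The deposited table held an expected count per gene and library, that is, an estimated read number that need not be whole, with no normalization, per the file headers and the values. Per the submitters' processing notes, HISAT2 2.0.4, StringTie 1.2.1, Bowtie2 2.2.6 and RSEM 1.2.12 were used with genome build rn6, with no role or order given. The table listed 13554 genes by Entrez gene identifier, of which 5115 carried a transcript assembled by the submitters' pipeline beside the annotated ones, and 3.9% of the values were not whole numbers. Gene symbols were taken from the table, and 13482 identifiers were matched to the RefSeq gene table of assembly GRCr8, which was used for names and neighbours. The build differs from rn6, so no coordinates are given. Whether reads were counted by strand is not given in the sources used here, so reads of overlapping genes cannot be told apart.

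The expected counts were rounded to whole numbers, which left 1 gene at 0 in all libraries. Genes were filtered with filterByExpr by tissue at its default settings, which left 11202 tested and 2352 untested. The libraries were scaled by TMM, and each gene was tested for articular against xiphoid cartilage with the edgeR 4.0.16 quasi-likelihood test (glmQLFit with robust estimation and glmQLFTest) in R 4.3.3, with tissue as the model's only term and Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05. All p-values are 2-sided. The fit had 2 residual degrees of freedom, a median of 10 prior degrees of freedom and a biological coefficient of variation of 14.1%. A positive log2 fold change means higher in articular cartilage, and its standard error was taken as its size divided by the square root of the test's F. CPM are the usual library-size normalised counts after TMM scaling. The totals per library ranged from 7351006 to 8434820 counts. For a gene with no count in a tissue, the fold is a lower bound computed against 3 counts over both libraries of that tissue. For 1 to 3 counts, the ratio of counts is given with an exact conditional binomial interval at 95%. No explicit correction for transcript length was made, which cancels within a gene when its transcripts are the same in both tissues.

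Before the data were examined, 34 gene lists were fixed from general knowledge of cartilage, positional identity, metabolism and the other cell types that dissected cartilage can hold. They held 635 entries, of which 544 were matched to the table. The lists with at least 3 tested members, 32 in all, were tested with camera (limma 3.58.1, preset correlation 0.01), with adjustment over the lists, and again with an estimated correlation and with fry. Of the list of mitochondrially encoded genes 0 members were analysed here, and the sex-linked list had 1 tested member. Counts of members past the threshold are given over all genes tested and adjusted over the list alone.

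Named genes were chosen by a rule fixed in advance. It took the 6 genes with the largest fitted change in each direction among those past the threshold with at least 10 CPM in the higher tissue, a proper symbol and no overlap of libraries between tissues. It then took the next 6 in each direction outside the marker lists, 12 genes named in advance, and up to 4 members of each list with the lowest adjusted p. The rule gave 146 genes, of which the text gives those that best describe each group. List members that went against their list or did not pass, and Cnmd, Fmod, Erg, Clu, Runx2, Tbx4, Sparc and Nt5dc1, were named after their values were seen. Genes with near-identical copies, such as globins, defensins, myosin heavy chains and Eif2s3y, are uncertain, because reads can be split between copies. Col10a1, one of the 12 genes, was not analysed here.

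The alternatives were RLE factors, upper-quartile factors, library sizes alone, no low-count filter, a mean CPM of at least 5, DESeq2 1.42.0, limma-voom, a replicate block, glmTreat against a fold of 1.5, leaving out the 182 listed markers of other cell types, and leaving out each library in turn. Leaving out the ribosomal RNA rows (Rn45s, Rn28s and Rn18s) was added after seeing the data. A test of FPKM or TPM values had been planned for tables that hold them and was not run. Gene Ontology biological process terms, as annotated in the processed table, with 15 to 300 tested genes were tested with camera as an addition chosen after seeing the data.

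The procedure was tested on simulated data with the means and library sizes of these samples and 11039 genes tested. For articular against xiphoid cartilage it recovered 68.7% of 99 genes changed 2-fold and 91.9% of 99 genes changed 4-fold, with 8 false calls, or 4.8% of calls, and 0 calls in the wrong direction. Few genes were changed in the simulation, whereas 49.5% were called in the data, and its libraries were drawn independently. These shares therefore do not carry over directly to the data. Replicates of a tissue differed by more than sampling noise (chi-square per degree of freedom of 26.8 in articular and 18.9 in xiphoid cartilage), so each library was counted once. Groups of 2 libraries are too small for a test of outlying samples.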

Results

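RNA was sequenced from 2 cartilages of Sprague-Dawley rats aged 8 to 10 weeks. Articular cartilage covers the bone ends in joints, and xiphoid cartilage forms the lower tip of the sternum. Each tissue had 2 libraries, and the value of each gene was an estimated read count. The total was 8394769 and 7785225 counts in the articular libraries and 8434820 and 7351006 in the xiphoid libraries. Across genes, Spearman's rho was 0.985 between the articular libraries, 0.99 between the xiphoid libraries and 0.878 to 0.89 between tissues, where genes are not independent replicates. Col2a1, which encodes the chain of type II collagen, took 10.3% and 8.57% of the counts of the articular libraries. In the xiphoid libraries the highest gene was Sparc, which encodes a matrix glycoprotein, with 2.55% and 2.51%. The labels do not name the joint, the sex or the animals behind each library, so the p-values of genes measure the spread between these samples, which may be technical.

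The comparison asked how the transcript profiles of the 2 cartilages differed. Articular cartilage carried far more transcript of Prg4, which encodes the joint lubricant lubricin, of mineralization genes such as Mmp13, Alpl and Ihh, and of bone and marrow cell markers. Xiphoid cartilage carried far more elastin (Eln), Matn1 and Ucma transcript, more of most tested Hox genes of groups 1 to 8, and more of the markers of skeletal muscle and fat. Of 11202 genes tested, 2799 were higher in articular cartilage and 2745 were higher in xiphoid cartilage at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), together 49.5% of the genes tested. A fold change above 2 was fitted for 1744 and 1529 of them, and one above 8 for 328 and 445. Among the called genes, 58 had no count in either xiphoid library and 78 had none in either articular library. At this depth a count of 0 over both libraries of a tissue allows up to 3 counts, or 0.186 CPM in articular and 0.19 CPM in xiphoid cartilage, and such floors and the intervals below cover counting error only. Levels below are CPM as mean ± SD with n = 2, and adjusted p-values of genes are from the same edgeR test.

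Of 32 gene lists tested as sets with camera, 11 were higher in articular and 9 in xiphoid cartilage (adjusted over the 32 lists, preset correlation 0.01). With the preset, camera compares a list's genes with all other tested genes. Its p-values then rest on the number of genes, so very small values do not measure the spread between libraries. With the correlation between genes estimated from these 4 libraries, 0 lists passed, 13 had an unadjusted p under 0.05 and the lowest adjusted p was 0.0705. That version uses the fit's 2 residual degrees of freedom, so its larger p-values need not reflect correlation. The estimated correlation was -0.059 for the hypertrophy list and 0.159 for the skeletal muscle list, against the preset 0.01. Fry asks whether a list's own genes moved on balance one way, without comparing them with other genes. With 49.5% of all tested genes called, such a test can pass many lists. Fry called 26 lists, of which camera had not called 6. Toward articular cartilage these were matrix proteases (fry adjusted p = 0.0145), hyaline cartilage matrix (0.018) and macrophage markers (0.0272). Toward xiphoid cartilage they were endothelial markers (0.006), BMP and TGF-beta signalling (0.0147) and Schwann cell and nerve markers (0.0272). For matrix proteases (-0.57) and for BMP and TGF-beta signalling (0.15) the median log2 fold change lay on the side opposite to fry's call. The plot of list members gives the change of each gene.

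**Figure D1:**
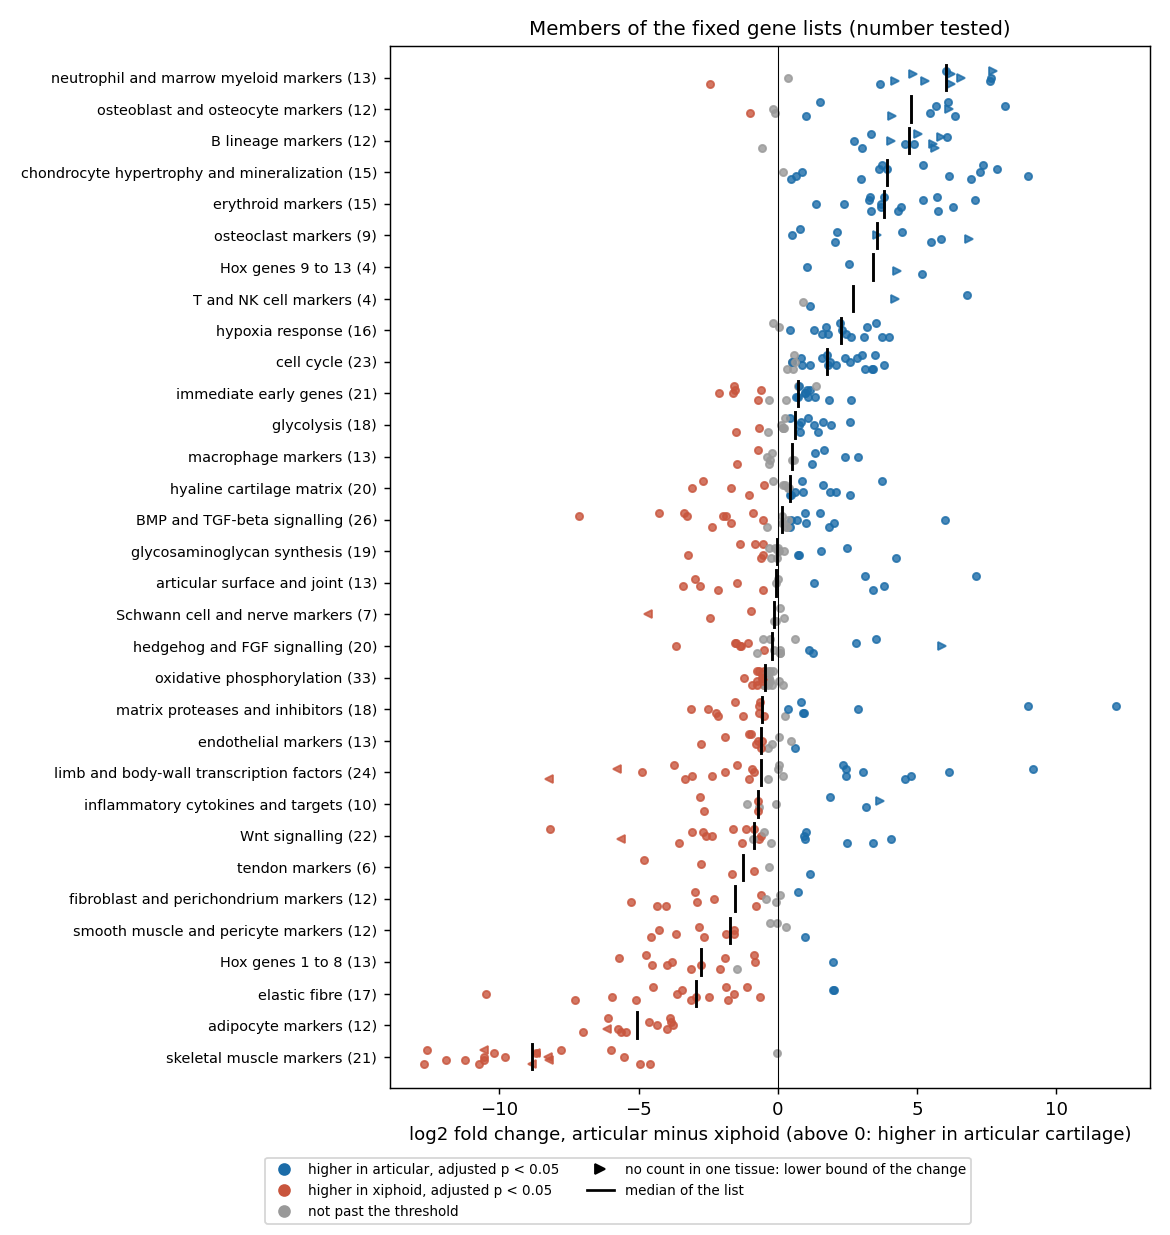
Each point is the log2 fold change (articular minus xiphoid) of 1 tested member of a gene list, with the number of tested members in parentheses, the list's median as a black bar, and triangles as lower bounds for genes with no count in a tissue. The skeletal muscle list lies farthest to the xiphoid side, with a median of -8.84, and the neutrophil and marrow myeloid list farthest to the articular side, with a median of 6.02.

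The hyaline cartilage matrix list was split between the tissues. Col2a1 (Entrez gene 25412) was at 94530 ± 12530 CPM in articular and 15600 ± 1050 in xiphoid cartilage, 6.06-fold higher in articular cartilage (log2 fold change 2.60, SE 0.17, adjusted p = 1.58e-07). Hapln1, the link protein that ties aggrecan to hyaluronan, was 4.29-fold higher in articular cartilage (2440 ± 316 against 568.9 ± 46.1 CPM, adjusted p = 7.23e-07). Matn1 (Entrez gene 297894), a matrilin of cartilage outside joints, was 8.39-fold higher in xiphoid cartilage (325 ± 33.2 against 38.8 ± 0.681 CPM, log2 fold change -3.07, SE 0.16, adjusted p = 1.8e-08). Ucma, a vitamin K dependent protein secreted by chondrocytes, was 6.45-fold higher in xiphoid cartilage (4385 ± 162 against 680 ± 20.6 CPM, adjusted p = 5.63e-08). The xiphoid side also held Cnmd, an inhibitor of vessel growth, at 2631 ± 130 against 823 ± 27.9 CPM (adjusted p = 2.49e-06) and Fmod, a collagen-binding proteoglycan, at 4104 ± 474 against 1974 ± 191 CPM (adjusted p = 1.95e-04). Of the list's 20 tested members, 10 were higher in articular cartilage, 5 were higher in xiphoid cartilage and 5 did not pass, with the same counts adjusted over the list alone, and the list as a set did not pass (camera adjusted p = 0.412).

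Aggrecan (Acan) and cartilage oligomeric matrix protein (Comp) differed little. Acan was at 8118 ± 441 CPM in articular and 5792 ± 202 in xiphoid cartilage (1.40-fold, adjusted p = 0.019), and Comp at 2237 ± 3.74 and 3133 ± 54.9 CPM (1.40-fold higher in xiphoid cartilage, adjusted p = 0.0167). Neither call held throughout. The adjusted p of Acan was 0.0692 without articular replicate 1, 0.127 without xiphoid replicate 1 and 0.193 without xiphoid replicate 2, and that of Comp was 0.128 and 0.173 without xiphoid replicates 1 and 2. Their log2 fold changes stayed close, at 0.43, 0.53 and 0.46 for Acan (0.49 with all libraries) and at -0.49 and -0.46 for Comp (-0.49 with all libraries). Sox9, the master regulator of chondrocytes, was at 213.8 ± 24.1 CPM in articular and 189.2 ± 39.5 in xiphoid cartilage (log2 fold change 0.18, SE 0.17), and did not pass (adjusted p = 0.415). The glycosaminoglycan synthesis list had 5 members higher in articular cartilage, 6 higher in xiphoid cartilage and 8 did not pass, the same adjusted over the list alone. Its median log2 fold change was -0.03, its mean 0.12 and its camera adjusted p 0.958 toward xiphoid cartilage. Its members with the lowest adjusted p were Extl1, a heparan sulfate glycosyltransferase, at 67.5 ± 1.38 CPM in articular and 628 ± 30.8 in xiphoid cartilage (adjusted p = 8.69e-09), and Csgalnact2, which starts chondroitin sulfate chains, at 262 ± 31.5 against 46.6 ± 5.27 CPM (adjusted p = 1.57e-07). Papss2, which makes the sulfate donor, was 2.56-fold higher in xiphoid cartilage (adjusted p = 4.31e-05). Chst3, a chondroitin sulfotransferase, was at 9.86 ± 4.67 against 0.48 ± 0.485 CPM (log2 fold change 4.26, adjusted p = 8.04e-05), which was 6.03 without xiphoid replicate 1 and 3.58 without xiphoid replicate 2.

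Genes of the joint surface went both ways. Prg4 (Entrez gene 289104) was at 10060 ± 1888 CPM in articular and 73.3 ± 19.98 in xiphoid cartilage, 137-fold higher in articular cartilage (log2 fold change 7.10, SE 0.27, adjusted p = 1.1e-09). Cilp, a matrix protein of the middle layer of articular cartilage, was 14.1-fold higher in articular cartilage (350 ± 26.0 against 24.7 ± 4.76 CPM, adjusted p = 8.11e-09), and Erg, a transcription factor of joint-forming cells, was at 64.4 ± 6.40 against 26.3 ± 3.88 CPM (adjusted p = 7.77e-05). In the other direction, Thbs4, a thrombospondin of tendon and muscle, was 10.6-fold higher in xiphoid cartilage (354 ± 21.7 against 33.5 ± 1.25 CPM, adjusted p = 6.81e-09). Dkk3 was 6.89-fold (adjusted p = 4.64e-08) and Clu, the secreted chaperone clusterin, 7.86-fold higher in xiphoid cartilage (adjusted p = 4.67e-08). Of 13 tested members, 5 were higher in articular cartilage, 6 were higher in xiphoid cartilage and 2 did not pass, the same adjusted over the list alone. The list's median was -0.07, its mean 0.41 and its camera adjusted p 0.926 toward articular cartilage.

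Genes of chondrocyte hypertrophy and mineralization were higher in articular cartilage as a set (camera adjusted p = 7.08e-29, adjusted p = 0.0705 with an estimated correlation). Of 15 tested members, 14 were higher in articular cartilage and Slc20a1, a phosphate transporter, did not pass, with the same count adjusted over the list alone, and the median log2 fold change was 3.92. Mmp13, the collagenase that degrades type II collagen, was at 736.5 ± 95.7 CPM in articular and 1.41 ± 0.832 in xiphoid cartilage (log2 fold change 8.98, SE 0.29, adjusted p = 3.75e-10), which was 9.79 without xiphoid replicate 1. Alpl, the alkaline phosphatase of mineralizing matrix, was 121-fold higher (918.9 ± 16.6 against 7.56 ± 0.546 CPM, adjusted p = 1.31e-10). Ihh, the hedgehog ligand of prehypertrophic chondrocytes, was 163-fold higher (228 ± 27.5 against 1.36 ± 0.569 CPM, adjusted p = 7.16e-10), and Pth1r, the receptor of parathyroid hormone related protein, was 36.7-fold higher (adjusted p = 5.14e-10). Ibsp, a bone sialoprotein, was at 1927 ± 736 against 8.20 ± 1.71 CPM (adjusted p = 3.22e-08), and Runx2, the transcription factor of hypertrophy and bone formation, was at 135 ± 40.9 against 17.1 ± 3.10 CPM (adjusted p = 6.18e-07). Several of these genes are also expressed by osteoblasts, and markers of bone cells and marrow were higher in the same articular libraries, with erythroid markers at 0.876% and 0.893% of counts against 0.0736% and 0.0795%. Col10a1 was not analysed here.

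The matrix proteases and their inhibitors were mixed. Mmp9, the gelatinase of osteoclasts and neutrophils, was at 639 ± 52.1 CPM in articular cartilage against 2 counts in all in xiphoid cartilage, a ratio of 5040 with an exact 95% counting interval of 1390 to 41600 (adjusted p = 7.04e-11). Mmp2 was 4.67-fold (adjusted p = 1.79e-07) and the protease inhibitor A2m 4.42-fold higher in xiphoid cartilage (adjusted p = 3.17e-07). Of 18 tested members, 7 were higher in articular cartilage, 10 were higher in xiphoid cartilage and 1, Adamts5, did not pass, with the same counts adjusted over the list alone. The median was -0.57, the mean 0.66 and the camera adjusted p 0.552 toward articular cartilage.

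Elastic fibre genes were higher in xiphoid cartilage as a set (camera adjusted p = 1.26e-17, adjusted p = 0.0705 with an estimated correlation). Eln (Entrez gene 25043) was at 20530 ± 2744 CPM in xiphoid and 14.2 ± 2.53 in articular cartilage, 1438-fold higher (log2 fold change -10.49, SE 0.26, adjusted p = 7.04e-11). Mfap4, a microfibril-associated protein, was at 646 ± 72.0 against 4.21 ± 2.23 CPM (log2 fold change -7.27, adjusted p = 3.52e-09), which was -7.93 without articular replicate 2. Loxl1, an elastin cross-linking enzyme, was 22.5-fold (adjusted p = 2.53e-09) and Efemp1, a fibulin, 33.7-fold higher (adjusted p = 3.68e-09). Of 17 tested members, 15 were higher in xiphoid cartilage, also when adjusted over the list alone. The other 2 were higher in articular cartilage: Lox, a cross-linking enzyme of collagen and elastin, at 2085 ± 512 against 531 ± 77.2 CPM (adjusted p = 5.18e-06), and Emilin1, an elastin microfibril interface protein, at 302.5 ± 68.5 against 74.8 ± 15.6 CPM (adjusted p = 4.64e-06). The list took 2.63% and 2.23% of counts in the xiphoid libraries against 0.262% and 0.328% in the articular libraries. Eln alone accounted for most of the xiphoid share. Fibroblast and smooth muscle markers were higher in the same xiphoid libraries, with fibroblast and perichondrium markers at 1.87% and 1.72% of counts against 0.223% and 0.231%. The gelsolin gene Gsn alone, at 13310 ± 806 against 345 ± 9.83 CPM, made up most of that xiphoid share.

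**Figure D2:**
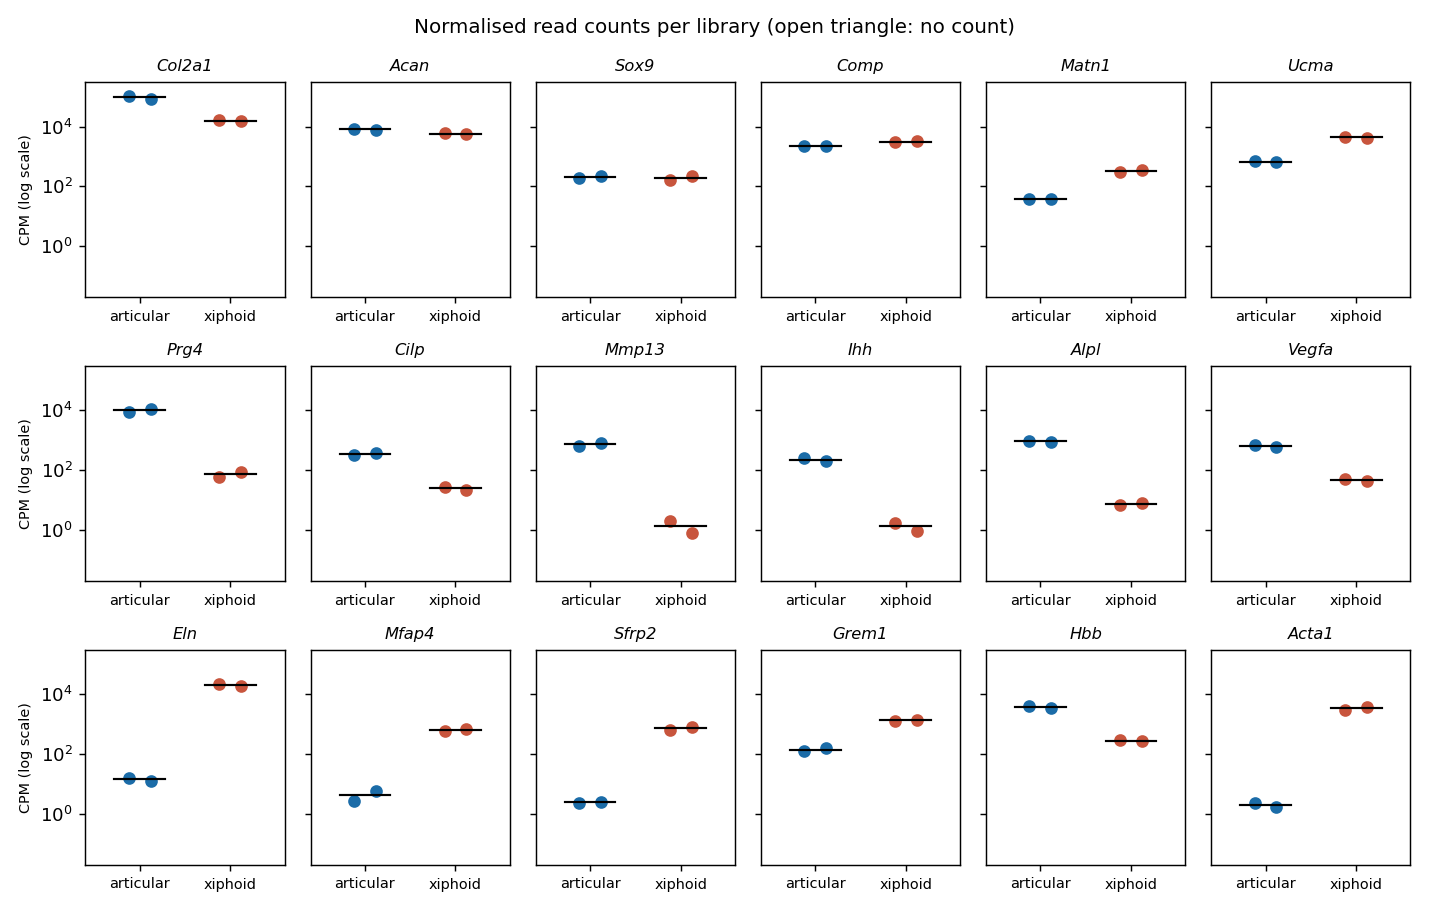
Normalised read counts of 18 genes (CPM, log axis), with 1 point per library and a bar at the tissue mean. Col2a1 and Prg4 sit higher in both articular libraries, Eln, Matn1 and Acta1 sit higher in both xiphoid libraries, and the libraries of both tissues overlap for Sox9.

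Among signalling genes, Wnt pathway genes were higher in xiphoid cartilage as a set (camera adjusted p = 0.00971, adjusted p = 0.286 with an estimated correlation). In this list, 13 of 22 tested members were higher in xiphoid cartilage, 6 were higher in articular cartilage and 3 did not pass, the same adjusted over the list alone. The members that were higher in xiphoid cartilage included secreted Wnt inhibitors as well as receptors. Sfrp2, a secreted Wnt-binding protein, was 293-fold higher in xiphoid cartilage (731 ± 120 against 2.48 ± 0.125 CPM, adjusted p = 1.62e-10), Sfrp4 was 11.7-fold higher (adjusted p = 1.73e-07) and the receptor Fzd4 was 8.48-fold higher (adjusted p = 1.24e-06). Dkk1, another Wnt inhibitor, was 16.8-fold higher in articular cartilage (41.8 ± 7.18 against 2.51 ± 0.718 CPM, adjusted p = 1.57e-07). Fibroblast, skeletal muscle and adipocyte markers were higher in the same xiphoid libraries. Fibroblast and perichondrium markers were at 1.87% and 1.72% of counts against 0.223% and 0.231%, with Gsn as most of the xiphoid share (values above). Skeletal muscle markers were at 1.14% and 1.13% against 0.0309% and 0.0243%, and adipocyte markers at 0.402% and 0.342% against 0.0143% and 0.0127%.

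The BMP and TGF-beta list did not pass as a set (camera adjusted p = 0.524 toward xiphoid cartilage, median 0.15, mean -0.44). In this list, 9 of 26 tested members were higher in articular cartilage, 10 were higher in xiphoid cartilage and 7 did not pass, the same adjusted over the list alone. Grem1, a BMP antagonist, was 9.51-fold higher in xiphoid cartilage (1355 ± 51.4 against 142.5 ± 21.2 CPM, adjusted p = 1.92e-08). Bmp5 was 19.5-fold higher in xiphoid cartilage (adjusted p = 4.01e-08), and the receptor Bmpr1b was at 19.6 ± 0.13 CPM there against 2 counts in all in articular cartilage, a ratio of 158 with an exact 95% counting interval of 43.3 to 1310. Bmp3 was 64.5-fold higher in articular cartilage (33.6 ± 4.05 against 0.50 ± 0.125 CPM, adjusted p = 3.31e-08). Hedgehog targets and FGF pathway genes parted within their list, which did not pass as a set (camera adjusted p = 0.79 toward articular cartilage, median -0.20, mean 0.32). The hedgehog targets Ptch1 (179 ± 21.2 against 25.7 ± 0.635 CPM, adjusted p = 5.91e-08), Gli1 and Hhip were higher in articular cartilage, the last at 11.4 ± 0.83 CPM with no count in xiphoid cartilage and so at least 60.0-fold higher (adjusted p = 1.86e-06). Gli1 was at 18.9 ± 4.22 against 1.597 ± 0.902 CPM (log2 fold change 3.52, adjusted p = 7.85e-06), which was 4.29 without xiphoid replicate 1. Fgfr3, the receptor that restrains chondrocyte growth, was 2.56-fold higher in xiphoid cartilage (1024 ± 121 against 399.9 ± 42.0 CPM, adjusted p = 2.32e-05). Of 20 tested members, 5 were higher in articular cartilage, 7 were higher in xiphoid cartilage and 8 did not pass, with the same counts adjusted over the list alone.

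The tested Hox genes, which record position along the body axis, largely split by group number. Of 23 listed genes of groups 1 to 8, 15 were matched and 13 tested. Of 16 listed genes of groups 9 to 13, 8 were matched and only 4 tested, so the split rests on part of the family. Among 13 tested Hox genes of groups 1 to 8, 11 were higher in xiphoid cartilage (12 adjusted over the list alone), 1 was higher in articular cartilage and 1 did not pass (camera adjusted p = 5.35e-05, adjusted p = 0.121 with an estimated correlation). Hoxa2 was at 20.2 ± 1.91 CPM in xiphoid and 0.877 ± 0.394 in articular cartilage (22.8-fold, adjusted p = 6.94e-07). Hoxb3 was at 15.2 ± 4.89 and 0.551 ± 0.235 CPM (26.8-fold, adjusted p = 2.97e-06), and Hoxc8 at 47.7 ± 11.3 and 7.09 ± 1.48 (6.72-fold, adjusted p = 1.89e-06). Hoxb7 was at 15.9 ± 0.168 and 1.09 ± 0.821 CPM (log2 fold change -3.82, adjusted p = 8.05e-06), which was -4.91 without articular replicate 1 and -3.23 without articular replicate 2. The exception was Hoxd4, at 15.9 ± 4.63 CPM in articular and 3.996 ± 2.16 in xiphoid cartilage (adjusted p = 6.87e-04). All 4 tested Hox genes of groups 9 to 13 were higher in articular cartilage, also when adjusted over the list alone (camera adjusted p = 9e-04, adjusted p = 0.149 with an estimated correlation). Hoxc10 was at 32.8 ± 3.05 CPM in articular and 0.891 ± 0.0961 in xiphoid cartilage (36.3-fold, adjusted p = 4.66e-08), and Hoxd9 and Hoxc9 were 5.93-fold (adjusted p = 2.59e-05) and 2.07-fold higher in articular cartilage (adjusted p = 0.0032). Hoxc11 was at 3.66 ± 0.272 CPM with no count in xiphoid cartilage, at least 19.3-fold higher (adjusted p = 1.35e-04). The fibroblast, muscle and fat markers (values above) were higher in the same xiphoid libraries as Hox groups 1 to 8, and the erythroid and osteoclast markers (values below) in the same articular libraries as groups 9 to 13.

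Transcription factors of limb and body-wall patterning also differed gene by gene. Tbx5, the forelimb and heart T-box factor, was at 10.2 ± 0.149 CPM in xiphoid cartilage with no count in articular cartilage, at least 55.2-fold higher (adjusted p = 2.61e-06), while Tbx4, the hindlimb T-box factor, was at 6.40 ± 0.935 CPM in articular and 0.764 ± 0.0823 in xiphoid cartilage (adjusted p = 1.56e-04). Pitx1, a hindlimb homeobox factor, was 1.92-fold higher in xiphoid cartilage (75.1 ± 6.04 against 39.1 ± 5.04 CPM, adjusted p = 5.36e-04). Alx1, a homeobox factor of facial mesenchyme, was at 55.6 ± 4.11 CPM in xiphoid cartilage with no count in articular cartilage, at least 298-fold higher (adjusted p = 9.49e-09). On the articular side, Irx3 was 23.5-fold higher (132 ± 16.3 against 5.62 ± 0.20 CPM, adjusted p = 3.68e-09). Barx1, a homeobox factor of joint and facial mesenchyme, was at 155 ± 6.13 against 0.274 ± 0.388 CPM (log2 fold change 9.17, adjusted p = 3.02e-09), which was 8.11 without xiphoid replicate 1, and the 4 xiphoid counts were all in replicate 2. Shox2, a limb homeobox factor, was at 32.2 ± 5.47 against 0.46 ± 0.318 CPM (log2 fold change 6.13, adjusted p = 8.42e-08), which was 5.53 without xiphoid replicate 1 and 7.02 without xiphoid replicate 2. Of 24 tested members, 8 were higher in articular cartilage, 12 were higher in xiphoid cartilage and 4 did not pass, the same adjusted over the list alone. The list did not pass as a set (camera adjusted p = 0.926 toward articular cartilage, median -0.62, mean -0.42).

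**Figure D3:**
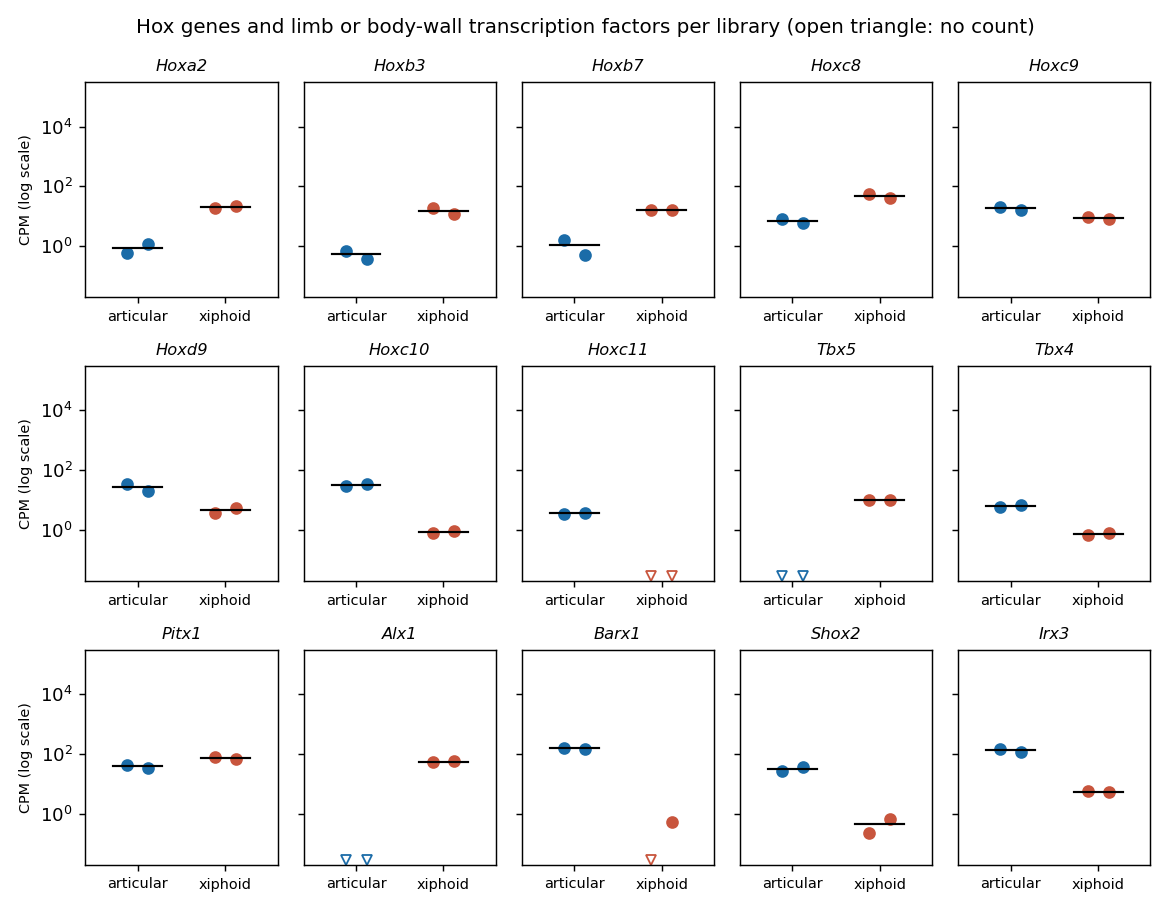
Normalised read counts (CPM, log axis) of 15 Hox and patterning genes, with 1 point per library, a bar at the tissue mean, and open triangles for libraries with no count. Tbx5 and Alx1 have no count in either articular library and Hoxc11 has none in either xiphoid library.

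Genes of the hypoxia response were higher in articular cartilage as a set (camera adjusted p = 1.67e-12, adjusted p = 0.085 with an estimated correlation). In this list, 14 of 16 tested members were higher and 2, Ddit4 and Pfkfb4, did not pass, the same adjusted over the list alone. Vegfa, the vessel growth factor, was 13.4-fold higher (650 ± 81.1 against 48.4 ± 4.36 CPM, adjusted p = 6.57e-09). Car9, a carbonic anhydrase, was 9.25-fold higher (adjusted p = 4.67e-08), the collagen prolyl hydroxylase P4ha2 was 6.21-fold higher (adjusted p = 5.09e-08) and Stc2 was 11.5-fold higher (adjusted p = 9.74e-08). Glycolysis genes were also higher in articular cartilage as a set (camera adjusted p = 0.0187, adjusted p = 0.289 with an estimated correlation). In this list, 10 of 18 members were higher in articular cartilage, 2 were higher in xiphoid cartilage and 6 did not pass, the same adjusted over the list alone. Pgk1 was 3.09-fold (adjusted p = 2.62e-06), Eno2 5.96-fold (adjusted p = 6.17e-08) and the glucose transporter Slc2a1 2.73-fold higher in articular cartilage (adjusted p = 5.72e-06). The exceptions were Pfkm, the muscle phosphofructokinase, at 181 ± 4.14 CPM in xiphoid and 63.3 ± 11.5 in articular cartilage (adjusted p = 1.18e-05), and Pfkp, the platelet form (adjusted p = 0.00213). Erythroid and osteoclast markers were higher in the same articular libraries as these 2 sets, at 0.876% and 0.893% of counts against 0.0736% and 0.0795%, and at 0.146% and 0.149% against 0.0197% and 0.0183%.

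Oxidative phosphorylation genes were higher in xiphoid cartilage by small amounts, with a median log2 fold change of -0.48 (camera adjusted p = 0.0259, adjusted p = 0.389 with an estimated correlation). Of 33 tested members, 16 were higher in xiphoid cartilage (18 adjusted over the list alone), 0 were higher in articular cartilage and 17 did not pass. Ndufa4 was 2.31-fold (adjusted p = 2.71e-05), Cox5a 1.91-fold (adjusted p = 4.63e-04), Ndufv2 1.67-fold (adjusted p = 0.00123) and Cyc1 1.59-fold higher (adjusted p = 0.00245). The set did not pass without xiphoid replicate 1 (camera adjusted p = 0.0691). Skeletal muscle markers, at 1.14% and 1.13% of counts in the xiphoid and 0.0309% and 0.0243% in the articular libraries, were higher in the same xiphoid libraries.

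Cell cycle genes were higher in articular cartilage as a set (camera adjusted p = 3.29e-06, adjusted p = 0.102 with an estimated correlation). In this list, 18 of 23 tested members were higher (19 adjusted over the list alone), 0 were higher in xiphoid cartilage and 5 did not pass. Mki67, a marker of dividing cells, was 13.9-fold (23.9 ± 1.64 against 1.69 ± 0.265 CPM, adjusted p = 4.83e-07) and Top2a 10.6-fold higher (adjusted p = 3e-07), with Ccna2 and Ccnb2 10.5-fold and 5.94-fold higher (adjusted p = 3.43e-05 and 3.99e-05). Marrow cell markers were higher in the same articular libraries, with erythroid markers at 0.876% and 0.893% of counts against 0.0736% and 0.0795%. The immediate early genes did not pass as a set (camera adjusted p = 0.451). Of the 21 tested members, 11 were higher in articular cartilage (12 adjusted over the list alone), 6 were higher in xiphoid cartilage and 4 did not pass. Atf3 and Ier3 were 3.59-fold and 2.49-fold higher in articular cartilage (adjusted p = 6.49e-05 and 9.2e-05), while the nuclear receptor Nr4a1 and the phosphatase Dusp1 were 4.34-fold and 3.08-fold higher in xiphoid cartilage (adjusted p = 4.51e-07 and 2.6e-06). Inflammatory genes did not pass as a set (camera adjusted p = 0.552 toward xiphoid cartilage, median -0.70, mean 0.36). Of the 10 tested members, 3 were higher in articular cartilage, 4 were higher in xiphoid cartilage and 3 did not pass, the same adjusted over the list alone. Tnfaip6, a hyaluronan-binding protein, was at 9.63 ± 1.31 CPM in xiphoid and 1.36 ± 0.282 in articular cartilage (adjusted p = 5.59e-05). Ptgs2, the inducible cyclooxygenase, was at 2.46 ± 1.61 CPM in articular cartilage with no count in xiphoid cartilage, at least 12.7-fold higher (adjusted p = 0.00151). Without articular replicate 2 this bound was 6.93-fold and Ptgs2 did not pass the low-count filter, so it was not tested.

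Markers of bone and marrow cells were higher in articular cartilage. Osteoblast and osteocyte markers passed as a set (camera adjusted p = 3.11e-10, adjusted p = 0.102 with an estimated correlation). Of the 12 tested members, 9 were higher in articular cartilage, 1 (Pdpn) was higher in xiphoid cartilage and 2 (Col1a1 and Col1a2) did not pass, the same adjusted over the list alone. Bglap, which encodes osteocalcin, was 81.5-fold higher (461 ± 65.7 against 5.66 ± 0.521 CPM, adjusted p = 3.75e-10), the osteocyte protein Dmp1 282-fold higher (adjusted p = 7.81e-10) and the osteoblast factor Sp7 44.0-fold higher (adjusted p = 6.81e-09). All 9 tested osteoclast markers were higher, also when adjusted over the list alone (camera adjusted p = 4.57e-10, adjusted p = 0.0989 with an estimated correlation). Acp5, the tartrate-resistant acid phosphatase, was at 774 ± 19.1 against 17.0 ± 0.135 CPM (adjusted p = 3.75e-10), Ctsk was 4.10-fold higher (adjusted p = 3.18e-07) and Atp6v0d2, a proton pump subunit, was at 22.1 ± 1.11 CPM with no count in xiphoid cartilage, at least 116-fold higher (adjusted p = 1.67e-07).

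All 15 erythroid markers were higher in articular cartilage, also when adjusted over the list alone (camera adjusted p = 1.42e-20, adjusted p = 0.0705 with an estimated correlation). Hbb, a beta globin, was at 3687 ± 298 against 281.5 ± 9.66 CPM (adjusted p = 6.09e-09), although reads of the near-identical globin genes could have been split between copies. Of 13 neutrophil and marrow myeloid markers, 11 were higher in articular cartilage, 1 (Lcn2) was higher in xiphoid cartilage and 1 (Mpo) did not pass, the same adjusted over the list alone (camera adjusted p = 2.75e-11, adjusted p = 0.102 with an estimated correlation). The alarmin S100a8 was at 65.0 ± 0.725 against 0.304 ± 0.236 CPM (log2 fold change 7.62, adjusted p = 3.78e-09), which was 8.74 without xiphoid replicate 1. Camp, the cathelicidin, was at least 74.7-fold higher (adjusted p = 8.01e-07) and Prg2, an eosinophil granule protein outside the list, at least 97.6-fold higher (adjusted p = 3.93e-07), each with no count in xiphoid cartilage. The defensins Np4, Defa5 and RatNP-3b also had no count there and were at least 212-fold, 95.9-fold and 74.4-fold higher (adjusted p = 4.66e-08, 3.45e-07 and 9.18e-07), with reads that paralogs could share. B lineage markers were higher as a set (camera adjusted p = 1.36e-05, adjusted p = 0.149 with an estimated correlation). Of the 12 tested members, 11 were higher, also adjusted over the list alone, and 1 (Ebf1) did not pass. They included the precursor genes Vpreb1 and Dntt, at 9.502 ± 1.45 and 6.14 ± 0.221 CPM with no count in xiphoid cartilage, at least 50.2-fold and 32.3-fold higher (adjusted p = 4.32e-06 and 2.13e-05). Of 16 T and NK cell markers with counts, only 4 passed the low-count filter, and Cd3d, Cd3e, Cd3g and Cd8a were among those that did not. Of the 4 tested, 3 (Cd4, Zap70 and Nkg7) were higher in articular cartilage and 1 (Lck) did not pass. The counts were the same adjusted over the list alone (camera adjusted p = 0.00876, adjusted p = 0.364 with an estimated correlation). Macrophage markers did not pass as a set (camera adjusted p = 0.17). Of the 13 tested members, 5 were higher in articular cartilage, such as Tyrobp (5.32-fold, adjusted p = 9.44e-07) and Csf1r (2.49-fold, adjusted p = 7.51e-05), 2 (Cd14 and C1qc) were higher in xiphoid cartilage and 6 did not pass, the same adjusted over the list alone.

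Markers of muscle, fat and fibrous tissue were higher in xiphoid cartilage. Skeletal muscle markers passed as a set (camera adjusted p = 1.11e-78, adjusted p = 0.0705 with an estimated correlation). Of the 21 tested members, 20 were higher, also adjusted over the list alone, and the median log2 fold change was -8.84 with genes at 0 set to their bound. Acta1, skeletal actin, was at 3355 ± 457 CPM in xiphoid and 1.97 ± 0.427 in articular cartilage (1682-fold, adjusted p = 7.04e-11). Creatine kinase Ckm was at 1742 ± 11.3 against 0.253 ± 0.188 CPM (log2 fold change -12.69, adjusted p = 7.04e-11), which was -12.08 without articular replicate 1 and -13.65 without articular replicate 2. Pvalb, a calcium buffer of fast fibres, had no count in articular cartilage and was at least 1510-fold higher (adjusted p = 3.75e-10), as were the slow and fast myosins Myh7 and Myh2, at least 459-fold and 410-fold higher (adjusted p = 7.2e-09 and 5.59e-09), with reads that other myosin heavy chain genes could share. Myh4 and Tnnc2 had 1 and 2 counts in all in articular cartilage, for ratios of 7840 (exact 95% counting interval 1410 to 310000) and 4440 (1230 to 36700). These counts were all in articular replicate 2, and the ratios were 3780 and 2140 without articular replicate 1 and at least 1350 and 1530 without articular replicate 2. The exception was Tnni2, fast troponin I, at 239.5 ± 41.1 CPM in articular and 243 ± 14.2 in xiphoid cartilage (adjusted p = 0.925). Outside the list, the muscle genes Cox8b, Myot and Art1 had no count in articular cartilage and were at least 171-fold, 157-fold and 159-fold higher (adjusted p = 4.64e-08, 2.47e-07 and 7.27e-08), and the sarcomere protein Myoz1 had 1 count there, for a ratio of 2810 (exact 95% counting interval 503 to 111000), which was 1450 without articular replicate 2 and at least 451 without articular replicate 1. Clic3, a chloride channel protein, was at least 139-fold higher in xiphoid cartilage (adjusted p = 9.21e-08).

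All 12 adipocyte markers were higher in xiphoid cartilage, also when adjusted over the list alone (camera adjusted p = 5.91e-31, adjusted p = 0.0705 with an estimated correlation). Adipoq, the fat hormone adiponectin, was 127-fold higher (445 ± 14.1 against 3.49 ± 0.701 CPM, adjusted p = 2.19e-10), the lipid droplet protein Plin1 44.2-fold higher (adjusted p = 1.32e-09) and Pck1 67.9-fold higher (adjusted p = 5.14e-10). Fibroblast and perichondrium markers passed as a set (camera adjusted p = 8.3e-07, adjusted p = 0.102 with an estimated correlation). Of the 12 tested members, 8 were higher in xiphoid cartilage, 1 (Dcn) was higher in articular cartilage and 3 did not pass, the same adjusted over the list alone. Gsn, the actin-severing protein gelsolin, was at 13310 ± 806 against 345 ± 9.83 CPM (38.6-fold, adjusted p = 6.68e-10), and Postn, a matrix protein of periosteum and ligament, was 16.3-fold higher (adjusted p = 6.36e-09). Smooth muscle and pericyte markers passed as a set (camera adjusted p = 8.84e-05, adjusted p = 0.121 with an estimated correlation). Of the 12 tested members, 8 were higher in xiphoid cartilage, 1 (Rgs5) was higher in articular cartilage and 3 did not pass, the same adjusted over the list alone. The 2 with the lowest adjusted p were Des at 167 ± 3.12 against 8.79 ± 2.11 CPM (adjusted p = 7.19e-09) and Lmod1 (23.3-fold, adjusted p = 2.22e-08). Tendon markers passed (camera adjusted p = 0.0146, adjusted p = 0.227 with an estimated correlation, and 0.0565 with limma-voom). Of the 6 tested members, 4 were higher in xiphoid cartilage, 1 (Egr1) was higher in articular cartilage and 1 (Kera) did not pass, the same adjusted over the list alone. Tnmd, a tendon membrane protein, was at 62.5 ± 1.46 against 2.23 ± 0.0632 CPM (adjusted p = 7.49e-09). Endothelial markers did not pass as a set (camera adjusted p = 0.103, and 0.0424 with limma-voom). Of the 13 tested members, 8 were higher in xiphoid cartilage, such as Cldn5 (6.74-fold, adjusted p = 8.6e-07), 1 (Kdr) was higher in articular cartilage and 4 did not pass, the same adjusted over the list alone. Schwann cell and nerve markers did not pass as a set (camera adjusted p = 0.227). Of the 7 tested members, 3 were higher in xiphoid cartilage and 4 did not pass, the same adjusted over the list alone.

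Of the sex-linked list 1 gene could be tested, Eif2s3y, at 81.4 ± 6.28 CPM in articular and 35.7 ± 1.52 in xiphoid cartilage (adjusted p = 6.34e-05, and the same call adjusted over the list alone), with reads that its near-identical X-linked copy could share. Xist and Ddx3y were matched but did not pass the low-count filter. The sex of the animals, or a difference in sex between the tissues, therefore cannot be told from this list. Leaving out the markers of other cell types before scaling left 9 lists called of the 18 that could then be tested, and none of those 18 changed its call or direction. This took out the 182 marker genes alone and kept all other reads of those cells. It therefore cannot decide whether the remaining lists differ through other cell types. Ribosomal RNA rows took 0.38% and 1.07% of counts in articular replicates 1 and 2 and 0.44% and 1.42% in xiphoid replicates 1 and 2.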

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

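Leaving out the ribosomal RNA rows was chosen after seeing the data, and all other settings before. The counts of 2799 and 2745 genes became 1686 and 1538 with glmTreat, which asks for more than 1.5-fold. Without each library in turn they ranged from 2235 to 2952 for articular and from 2070 to 3041 for xiphoid cartilage. With the replicate number as a block they were 3344 and 3484, and under every setting the calls shared with the edgeR test kept their direction. Same-numbered libraries deviated together across 9393 genes (r = 0.352), but 2 pairs are too few to say that the numbers pair the samples, and the block kept 5537 of 5544 calls. With DESeq2 the counts were 2312 and 2303. Of the gene lists, 20 were called with camera, 19 to 20 without each library in turn, 9 when markers of other cell types were left out, which leaves 18 lists to test, and 0 with an estimated correlation. The planned test on FPKM or TPM was not run, because the table used here holds counts.

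Uncalled lists changed their side, and none passed there. For limb and body-wall transcription factors the camera adjusted p was 0.88 with no low-count filter, 0.867 and 0.844 without xiphoid replicates 1 and 2, and 0.528 with limma-voom, all toward xiphoid cartilage, and over all left-out libraries it ranged from 0.615 to 0.867. For glycosaminoglycan synthesis it was 0.966 at a mean CPM of at least 5, 0.868 without articular replicate 1, and 0.983 and 0.984 without xiphoid replicates 1 and 2, toward articular cartilage, and over all left-out libraries it ranged from 0.868 to 0.987. The articular surface list moved toward xiphoid cartilage without xiphoid replicate 1 (0.983; range over all left-out libraries, on either side, 0.46 to 0.983) and with limma-voom (0.792), where matrix proteases (0.546) and hedgehog and FGF genes (0.792) did so too. Sox9 had a log2 fold change of -0.01 without xiphoid replicate 1, in a range up to 0.42. The cause was not tested. Ptgs2 did not pass the low-count filter without articular replicate 2 and has no value there. With glmTreat 6 named genes no longer passed, Acan, Comp, Ndufv2, Cyc1, Nfkbia and Pecam1, by the construction of that test. Under RLE, upper-quartile and library-size scaling all 146 named genes and 32 lists kept their calls and directions. Depth limits genes near the floor of 3 counts. Of simulated 2-fold changes 68.7% were recovered, in a simulation with far fewer changed genes than were called in the data.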

Other observations

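The tests of Gene Ontology terms, of scaling, of a lower share of cartilage cells and of Col10a1 reads in Nt5dc1 were chosen only after the results were seen. Of 1098 Gene Ontology terms tested with camera, 13 were higher in articular and 13 in xiphoid cartilage, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.963. As for the lists, the version with an estimated correlation used the fit's 2 residual degrees of freedom. Fatty acid beta-oxidation, whose genes include the adipocyte markers Adipoq and Lep, had 21 of 30 genes higher in xiphoid and 1 in articular cartilage (camera adjusted p = 4.31e-04, adjusted p = 0.963 with an estimated correlation). Examples outside the fixed lists were Ech1 at 273 CPM in xiphoid and 78.1 CPM in articular cartilage (adjusted p = 1.2e-06) and Echs1 at 185 and 69.6 CPM (adjusted p = 8.94e-06), both enzymes of mitochondrial beta-oxidation. Fatty acid biosynthesis, which includes the adipocyte marker Lpl, had 20 of 34 genes higher in xiphoid and 1 in articular cartilage (camera adjusted p = 0.0197, adjusted p = 0.963 with an estimated correlation), with Fasn, fatty acid synthase, at 366 and 77.0 CPM (log2 fold change -2.25, SE 0.15, adjusted p = 1.36e-07). The terms were not tested without these markers. Both muscle and fat express such genes, and markers of both were higher in the same libraries.

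Genes of the unfolded protein response of the endoplasmic reticulum were higher in articular cartilage, with 14 of 24 higher, 0 higher in xiphoid cartilage and a median log2 fold change of 0.75 (camera adjusted p = 0.00454, adjusted p = 0.963 with an estimated correlation). Ddit3, a stress-induced transcription factor, was at 143 CPM in articular and 23.4 CPM in xiphoid cartilage (log2 fold change 2.61, SE 0.17, adjusted p = 1.06e-07). Ero1a, an oxidase of protein folding, was at 102 and 15.8 CPM (adjusted p = 9.85e-08), and Atf6, a sensor of misfolded protein, at 44.2 and 14.1 CPM (adjusted p = 2.37e-05). Osteoclast and erythroid markers were higher in the same articular libraries, with osteoclast markers at 0.146% and 0.149% of counts against 0.0197% and 0.0183%, and erythroid markers at 0.876% and 0.893% against 0.0736% and 0.0795%. Of 12 osteoblast and osteocyte markers, 9 were higher there, 1 was higher in xiphoid cartilage and 2, Col1a1 and Col1a2, did not pass. The list's summed share of counts was similar in both tissues, 1.05% and 1.1% against 1.01% and 1.03%. That sum follows the most abundant members and does not measure specific markers such as Bglap, at 461 ± 65.7 against 5.66 ± 0.521 CPM.

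Skeletal muscle transcripts in the xiphoid libraries, with Acta1 at 3355 CPM and Ckm at 1742 CPM, may come from muscle dissected with the cartilage. In a further muscle list that shares no gene with the list above, 85.7% of the tested genes (24 of 28) were higher in xiphoid cartilage, and 1, Klhl40, was higher in articular cartilage. That list held 37 genes, of which 33 were matched and 28 tested. The low-count filter keeps genes counted in either tissue alone, which can raise this share. Scaling between libraries as the whole cause is argued against, because it shifts all genes of a library alike. The median log2 fold change of the muscle list was -8.84, while that of all tested genes was -0.017, and -0.02 with library sizes alone. The library sizes after TMM scaling differed by at most 1.17-fold, but the fit divides this out, so it does not bear on the question. Tnni2, at 239.5 CPM in articular and 243 CPM in xiphoid cartilage, was the exception among the markers, for a reason that was not tested. Expression of muscle genes by xiphoid chondrocytes themselves was not tested and stays open.

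Bone and marrow transcripts in the articular libraries, with Hbb at 3687 CPM and Acp5 at 774 CPM, may come from subchondral bone with marrow taken with the cartilage. In a further marrow list that shares no gene with the lists above, 82.4% of the tested genes (14 of 17) were higher in articular cartilage, and 1, Tmod1, was higher in xiphoid cartilage. That list held 34 genes, of which 28 were matched and 17 tested. The low-count filter keeps genes counted in either tissue alone, which can raise this share. A lower share of cartilage cells in the articular libraries could raise markers of other cell types, but the skeletal muscle, adipocyte and fibroblast lists cannot test it. Their median log2 fold changes of -8.84, -5.04 and -1.53 could come from tissue taken with the xiphoid cartilage, whatever the cartilage share of the articular libraries. The hyaline cartilage matrix list went both ways, with 10 of 20 members higher in articular and 5 in xiphoid cartilage. A lower cartilage share therefore stays open. Mineralization genes such as Alpl and Ibsp are made by both hypertrophic chondrocytes and osteoblasts, so how much of their difference lies in cartilage cells stays open, as does a difference between the cartilages themselves.

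Nt5dc1, a nucleotidase domain gene, was at 14950 ± 1024 CPM in articular and 7010 ± 196.5 CPM in xiphoid cartilage (n = 2, 2.13-fold, edgeR adjusted p = 1.06e-04), and ranked 3 by mean CPM among the tested genes, whose median was 23.6 CPM. In the GRCr8 annotation the collagen gene Col10a1 lies within Nt5dc1, so reads of Col10a1 counted to Nt5dc1 are a candidate explanation. Of 332 genes nested in another listed gene 69.0% were listed, against 72.1% of 18201 other genes (ratio 0.956, Fisher's exact p = 0.217, 2-sided). Nested genes were thus not clearly absent more often. A nested gene that lost most of its reads to its host could still be listed, so this cannot decide whether reads were misassigned. Nt5dc1 had 3 transcripts assembled by the submitters' pipeline, and with no read positions here, its own expression and reads of Col10a1 cannot be told apart. The fold of Nt5dc1 is uncertain for that reason.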
